A study of Rattus norvegicus with 21 samples.

How the data were processed

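RNA was sequenced from the spinal cords of wild-type LEW/Crl rats aged 6 to 8 weeks that had received PBS, neomycin (NEO) or vancomycin (VANCO) into the trachea for 7 days. Per the labels' protocols, cords were homogenised and freed of myelin on a Percoll gradient. The pellet gave the total cord samples, and CD45low CD11b+ cells sorted from such material gave the microglia samples. There were 12 microglia libraries, 4 per treatment and numbered 1, 2, 3 and 5, and 9 total cord libraries, 3 per treatment and numbered 1, 2 and 3. The labels do not say whether each library came from 1 animal or from a pool, so p-values measure the spread between these samples.

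Each of the 21 deposited files holds raw counts for 32883 rat Ensembl gene IDs, and the values were whole numbers in every file. Per the submitters' processing notes, bcl2fastq 2.20.0.422, STAR 2.5.2a, featureCounts 1.5.0-p1 and the rn6 genome build were used. The gene annotation release, the strand setting and the treatment of reads with several alignments are not given in the sources used here, so counts of overlapping, antisense or near-identical genes are uncertain. The deposited counts were not normalised by the authors as far as the values show: library totals ranged from 9020480 to 22435887 in microglia and from 16769410 to 25114844 in total cord. The files do not pair the IDs with names, and 0 of the 32883 IDs matched the gene table used here. No gene is therefore named, and only 4 IDs are printed. The test of named gene lists, the interferon score and the rule for naming genes all needed symbols and were not run. That rule skipped Ensembl IDs, so the 4 printed IDs were chosen after their values were seen.

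Groups and replicate numbers were taken from the sample titles. No library was identical to another, and the 27 pairs of libraries within a group all differed by more than sampling noise, with a chi-square per degree of freedom from 8.35 to 221 over genes with at least 10 counts. All libraries were kept.

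Counts were tested in R 4.3.3 with edgeR 4.0.16. Genes were filtered with filterByExpr by group, libraries were scaled with TMM factors, and a robust quasi-likelihood F test was applied with Benjamini-Hochberg adjustment and a threshold of 0.05 on the adjusted p. The 12 microglia libraries formed 1 model (12570 genes tested) and the 9 total cord libraries another (14677 genes). A model of all 21 libraries (15546 genes) gave the comparison of the tissues in PBS animals and the tests of whether an antibiotic acted differently in microglia and cord. These models, the thresholds and the alternatives not said to be later choices were fixed before the data were examined, and their terms were the group means. This is called the unpaired model. A positive log2 fold change means a higher value in the group named first.

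The same replicate numbers occur in every treatment, and whether they pair the libraries was checked before any calls were compared. Deviations of log2 CPM (counts scaled to an equal library total, prior count 2) from the group means were correlated between libraries of different treatments across genes. Same-number libraries had r from 0.24 to 0.79 in microglia (12 pairs) and from 0.36 to 0.59 in cord (9 pairs). Libraries with different numbers had r from -0.55 to 0.34 in microglia and from -0.49 to 0.01 in cord. Deviations from group means cancel within a group, so positive same-number values push the others negative on average. The gap between same-number and other pairs is therefore partly built in. Each of the 12 microglia and 9 cord libraries correlated best with a library of its own number. The pairing thus comes from the data, since no label says what the number stands for. The same model with the replicate number as a block, called the paired model, was also fixed in advance, and its values stand beside the unpaired ones where they change a result. The common biological coefficient of variation fell with the block from 33.3% to 13.7% in microglia and from 12.1% to 5.88% in cord.

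The settings varied were DESeq2 1.42.0 with its own size factors, limma 3.58.1 with voom, RLE and upper quartile factors in edgeR, no filter on low counts, a filter of at least 1 CPM in as many libraries as the smallest group, a model of the compared groups only, a model of all 21 libraries, and leaving out each library in turn. Chosen after the data had been seen were the same changes within the paired model, every alternative for the correlations between tissues and between antibiotics, the division of the numbers between the antibiotics, leaving out all libraries of a number, the share of counts from cord-enriched genes as a covariate, and leaving out genes at least 8-fold higher in cord. Fold changes against the shared PBS libraries were compared with 20 simulated sets of unchanged groups, in which genes varied independently of each other.

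For describing the libraries, cord-enriched genes were those at least 64-fold higher in cord than in microglia of the PBS groups (1646 genes), and microglia-enriched genes those at least 8-fold higher in microglia (1304 genes). A share of counts in a single library is given with its 95% Wilson interval, and such intervals and floors of 3 counts cover counting error only. Group values are mean ± SD of CPM.

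The models were tested on simulated counts with means, depths and spread estimated from the real libraries and 200 changed genes in each of 3 sets. Differences between replicate numbers were part of these counts. A higher recovery with pairing therefore does not show that pairing suits the real libraries. For neomycin against PBS in microglia, the unpaired model recovered 12.1% of genes changed 1.5-fold, 49.2% of those changed 2-fold and 81.3% of those changed 4-fold among 12396 genes, and 0.36% of its calls were false. The paired model recovered 52.0%, 77.4% and 93.3%, with 3.74% of calls false. For the same comparison in cord (14581 genes), the unpaired model recovered 46.5%, 70.5% and 96.5%, with 0 false calls, and the paired model 81.0%, 91.0% and 100% at 1.5-, 2- and 4-fold, with 10.3% of calls false. For the difference between tissues in the effect of neomycin (15458 genes), recovery was 3.00%, 25.0% and 59.4% unpaired and 18.5%, 55.0% and 76.7% paired. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.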

Results

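Gene expression was measured in sorted spinal cord microglia (PBS, n = 4; NEO, n = 4; VANCO, n = 4) and in myelin-depleted total spinal cord (n = 3 for each treatment) after 7 days of intratracheal dosing, to see how antibiotics given this way affect the central nervous system. Neomycin and vancomycin are antibiotics of different classes, and PBS is the buffer control. Total counts in microglia were 11198001, 9020480, 17487066 and 22435887 for PBS replicates 1, 2, 3 and 5, 19298488, 10847891, 20066650 and 21353309 for NEO, and 15023952, 15319914, 20936827 and 14706297 for VANCO. In total cord they were 17842014, 18272910 and 16769410 for PBS replicates 1, 2 and 3, 18823791, 19012732 and 25114844 for NEO, and 17973630, 20075565 and 17711194 for VANCO. Between 15914 and 18857 genes had a count in each microglia library, and between 17937 and 19166 in each cord library.

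The sort was examined by comparing microglia with total cord in PBS animals. Of 15546 genes tested with edgeR, 13065 differed (6991 higher in microglia, 6074 higher in cord). This balance depended on the scaling: RLE factors moved the median log2 fold change of all genes by -0.50 and gave 5143 higher and 7367 lower, DESeq2 moved it by -0.50 and gave 5152 and 7011, and upper quartile factors moved it by -0.31 and gave 5844 and 6843. At TMM scaling 1304 genes were at least 8-fold higher in microglia and 3524 at least 8-fold higher in cord. The 1646 cord-enriched genes made up 28.7 to 33.2% of the counts in the cord libraries. In microglia their share was 0.0367 to 0.306% in 11 of the 12 libraries and 2.57% (95% Wilson interval, 2.56 to 2.58%) in NEO replicate 2. PBS replicate 2 and VANCO replicate 2 had 0.306% (0.303 to 0.310%) and 0.303% (0.301 to 0.306%). Microglia-enriched genes made up 33.4, 32.4 and 32.0% of counts in NEO replicates 1, 3 and 5, and 23.3% in NEO replicate 2. Their share was also low in PBS replicate 2, at 28.7% against 31.4 to 33.6% in the other PBS libraries. In VANCO replicate 2 it was 28.6% against 31.5 to 33.3%.

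**Figure D1:**
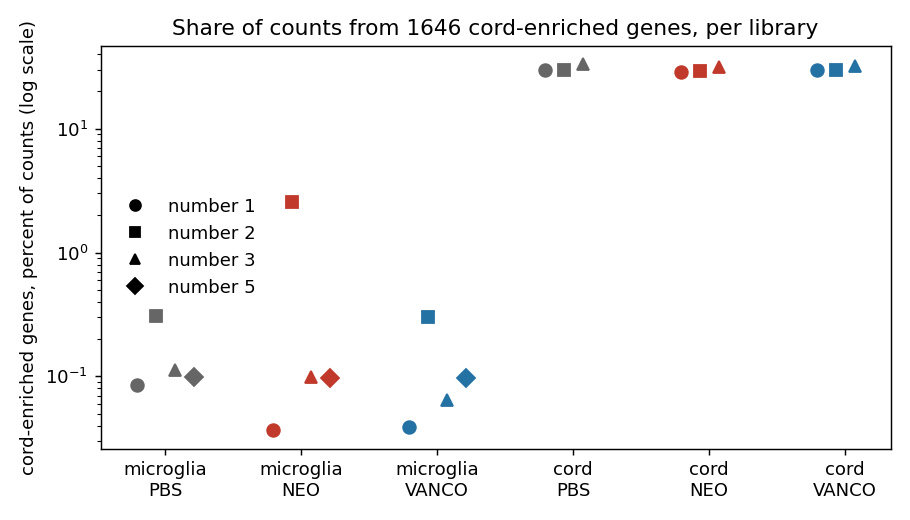
Share of counts from cord-enriched genes in each library, in percent on a log scale, by group on the horizontal axis; marker shapes give the replicate number and colours the treatment. NEO replicate 2 lies at 2.57%, above the other 11 microglia libraries, and the cord libraries lie between 28.7 and 33.2%.

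Neomycin was compared with PBS in microglia. The unpaired model called 5 of 12570 genes (4 higher, 1 lower), and 655 genes had an unadjusted p under 0.05. DESeq2 called 66 (52 higher, 14 lower) and limma-voom 4. Each of the 8 compared libraries mattered for the count of 5: it was 0 without NEO replicate 1 or 3 or any 1 of PBS replicates 1, 2, 3 and 5, 2 without NEO replicate 5, and 15 without NEO replicate 2. The paired model called 94 genes, 67 higher and 27 lower, and all 5 of the genes above were among them. The median log2 fold change of the 67 raised genes was 0.80 and that of the 27 lowered genes -0.68, and 27 raised and 4 lowered genes changed at least 2-fold. Leaving out 1 library changed the count of 94 to 300 (143 higher, 157 lower) without NEO replicate 2, to 44, 31 and 53 without NEO replicates 1, 3 and 5, and to 33, 49, 26 and 47 without PBS replicates 1, 2, 3 and 5. Leaving out every library of 1 number gave 20, 211 (115 higher, 96 lower), 0 and 19 genes without numbers 1, 2, 3 and 5. In the paired model DESeq2 called 168 genes higher and 146 lower, and edgeR with the cord-enriched share of each library as a covariate called 295 and 308, so the excess of raised genes depended on these choices. Of the 67 raised genes 47 were higher in microglia than in cord in PBS animals and 8 were higher in cord, and of the 27 lowered genes 23 and 2 were. Of all 15546 genes 45.0% were higher in microglia and 39.1% in cord by that test. These include genes not among the 12570 tested in microglia, and the balance depended on the scaling. The shares are therefore only a rough background for the 67 and 27 genes. The same microglia PBS libraries entered both tests, which tilts lowered genes towards higher in microglia and raised genes towards higher in cord.

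ENSRNOG00000036913 was raised by neomycin in microglia, with 352 ± 47.5 CPM (SD, n = 4) in NEO against 165 ± 22.9 CPM in PBS and 218 ± 17.9 CPM in VANCO. Its log2 fold change was 1.12 (SE 0.13, edgeR adjusted p 0.0139) unpaired and 1.11 (SE 0.12, adjusted p 0.00331) paired, and it was higher in 4 of 4 pairs. ENSRNOG00000017869 was lowered, with 574 ± 86.2 CPM in NEO, 958 ± 98.6 CPM in PBS and 810 ± 51.2 CPM in VANCO (SD, n = 4). Its log2 fold change was -0.73 (SE 0.11, edgeR adjusted p 0.0497) unpaired and -0.73 (SE 0.08, adjusted p 0.00331) paired, and it was lower in 4 of 4 pairs. NEO replicate 2 had the lowest value of ENSRNOG00000017869 among the 4 neomycin libraries (445 CPM, the others 610 to 623), and PBS replicate 2 the lowest of ENSRNOG00000036913 among the 4 PBS libraries (131 CPM, the others 174 to 181). In the unpaired model without 1 library at a time, the log2 fold change ranged from 1.02 to 1.22 for the first gene and from -0.77 to -0.64 for the second. The first gene kept its call without NEO replicate 2 or NEO replicate 5 and lost it without any 1 of the other 6 libraries. The second kept it without NEO replicate 2 and lost it without any 1 of the other 7.

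Vancomycin was compared with PBS in microglia. edgeR called 0 of 12570 genes in the unpaired model, where 108 had an unadjusted p under 0.05, and 0 in the paired model, where 365 had. limma-voom called 0 in either model, and DESeq2 called 5 (1 higher, 4 lower) unpaired and 38 (5 higher, 33 lower) paired. The paired edgeR count was 7, all lower, without PBS replicate 2 and 0 without any other single library. In the direct comparison of neomycin with vancomycin in microglia, edgeR called 0 genes unpaired, with 269 at an unadjusted p under 0.05, while DESeq2 called 16 and limma-voom 0. The paired model called 21 genes, 20 higher after neomycin and 1 lower. That count was 75 without NEO replicate 2, 3 and 11 without NEO replicates 3 and 5, and 1, 6, 1 and 4 without VANCO replicates 1, 2, 3 and 5; without all libraries of number 1, 2, 3 or 5 it was 4, 59, 0 and 3.

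Neomycin was compared with PBS in total cord. The unpaired model called 0 of 14677 genes in edgeR, with 400 at an unadjusted p under 0.05 and a lowest adjusted p of 0.0756. DESeq2 called 26 genes, all higher, and limma-voom 0. The paired model called 100 genes, 76 higher (median log2 fold change 0.62) and 24 lower (median -0.34), and 15 raised and 2 lowered genes changed at least 2-fold. The count of 100 was 65 without NEO replicate 1 and 57 without PBS replicate 3, and 398 (204 higher, 194 lower) and 59 (46 and 13) without all libraries of number 2 and of number 3. DESeq2 called 54 higher and 3 lower in its paired model, so the balance of directions depended on these choices. Of the 76 raised genes 40 were higher in microglia than in cord in PBS animals and 19 were higher in cord, while of the 24 lowered genes 4 and 17 were. Of all 15546 genes in that test 45.0% and 39.1% were, a rough background. The same cord PBS libraries entered both tests. Low PBS values of raised genes and high ones of lowered genes tilt these counts, so their contrast is partly built in.

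ENSRNOG00000022839 was raised in total cord, with 6.72 ± 2.02 CPM (SD, n = 3) in NEO, 1.79 ± 0.609 CPM in PBS and 2.08 ± 0.770 CPM in VANCO. Its log2 fold change against PBS was 1.92 (SE 0.30, edgeR adjusted p 0.128) unpaired and 1.92 (SE 0.19, adjusted p 2.14e-06) paired, and it was higher in 3 of 3 pairs. In microglia ENSRNOG00000022839 had 19.3 ± 16.3 CPM in NEO and 4.72 ± 3.58 CPM in PBS (SD, n = 4), with a paired log2 fold change of 1.84 (SE 0.31, edgeR adjusted p 0.0243) and an unpaired one of 2.04 (SE 0.66, adjusted p 0.816).

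Vancomycin was compared with PBS in total cord. edgeR called 0 of 14677 genes unpaired, with 124 at an unadjusted p under 0.05, and DESeq2 and limma-voom called 0 each. The paired model called 1 gene, ENSRNOG00000016837, which was lower, and DESeq2 and limma-voom called 0 in their paired models. ENSRNOG00000016837 had 0.802 ± 0.612 CPM in VANCO, 2.83 ± 2.42 CPM in PBS and 0.877 ± 0.726 CPM in NEO (SD, n = 3). Its paired log2 fold change was -1.79 (SE 0.27, edgeR adjusted p 0.00614) for vancomycin and -1.68 (SE 0.26, adjusted p 0.000592) for neomycin, and unpaired it was -1.80 (SE 1.16) and -1.76 (SE 1.14) with an adjusted p of 1 for both. The replicates numbered 3 had 2, 1 and 3 counts of ENSRNOG00000016837 in PBS, NEO and VANCO, so the gene was lower after vancomycin in 2 of 3 pairs and after neomycin in 3 of 3. The paired count of genes was 0 without PBS replicate 2, VANCO replicate 1 or VANCO replicate 2, 2 without PBS replicate 1 and 4 without PBS replicate 3. It was 3, 5 and 4 without numbers 1, 2 and 3.

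**Figure D2:**
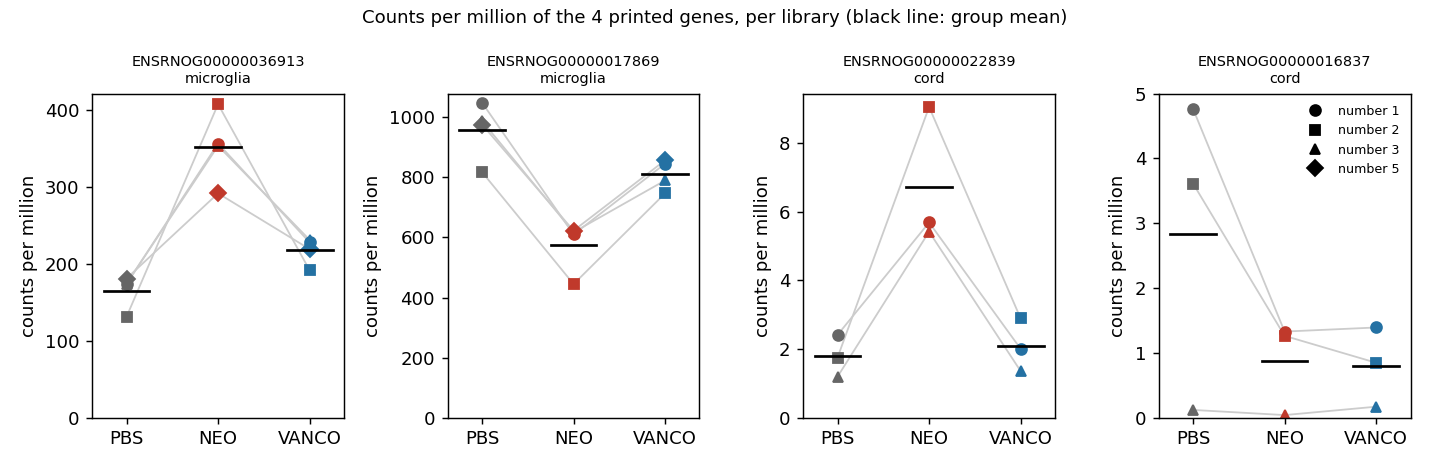
CPM of the 4 printed genes in each library by treatment, in microglia for the first and second panel and in total cord for the others; grey lines join libraries of 1 number and black lines mark group means. ENSRNOG00000036913 lies at 292 to 408 CPM in the 4 neomycin libraries and 131 to 181 CPM in the 4 PBS libraries, and number 3 lies near 0 in each treatment for ENSRNOG00000016837.

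Neomycin was compared directly with vancomycin in total cord. edgeR called 0 genes unpaired, with 331 at an unadjusted p under 0.05 and a lowest adjusted p of 0.0626, and the count was 1 without VANCO replicate 1. DESeq2 called 25 and limma-voom 0. The paired model called 64 genes, 57 higher after neomycin and 7 lower, and that count was 36 without VANCO replicate 1. Without all libraries of number 1 or 2 it was 42 and 129. Of the 57 genes 33 were higher in microglia than in cord in PBS animals and 12 were higher in cord. Of all 15546 genes in that test 45.0% and 39.1% were, a rough background.

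The effects of the antibiotics share the PBS libraries, which alone makes them correlate across genes. In microglia the neomycin and vancomycin log2 fold changes had r = 0.348 across 12570 genes, which are not independent replicates, and unchanged groups simulated against the same controls gave 0.511 (0.476 to 0.552). The covariance was 0.0556 against a simulated 0.0378. In the paired model r was 0.591 (simulated 0.510) and the covariance 0.0841 (simulated 0.0304). The simulated genes varied independently, so shifts that many genes of a single library share were missing from the simulated spread. The gaps to the simulated values therefore cannot be read as beyond chance. Without NEO replicate 2 the unpaired r was 0.822, and without VANCO replicate 2 it was 0.171. With separate pairs of PBS libraries for each antibiotic, the 6 possible divisions gave r from -0.199 to 0.203 and a mean covariance of -0.00901; these divisions ignore the replicate numbers, whose effects in the separate PBS pairs oppose each other and lower the covariance. With neomycin compared with PBS in 2 numbers and vancomycin with PBS in the other 2 numbers, so that no library was shared and numbers stayed paired, the 6 divisions gave r from -0.0812 to 0.591 and a mean covariance of 0.0668 (-0.0226 to 0.114). In total cord r was 0.478 (simulated 0.512) and the covariance 0.0149 (simulated 0.0142). The 67 genes raised by neomycin in microglia had a median vancomycin log2 fold change of 0.20, with 61 positive, and the 27 lowered genes one of -0.24, with 27 negative. The 76 genes raised by neomycin in cord had a median vancomycin log2 fold change of 0.06, with 54 positive, and the 24 lowered genes one of -0.10, with 23 negative. These signs also carry the shared controls. In cord 1 gene was lowered by both antibiotics in the paired model, where independent lists would share 0.00164 and unchanged groups simulated against the same controls shared 0.4 on average.

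The effects in microglia and total cord rest on separate libraries. Across the 11862 genes tested in both, the neomycin log2 fold changes had r = 0.102 and Spearman's rho = 0.183 unpaired, and r = 0.137 and rho = 0.196 paired. For vancomycin r was 0.037 and rho 0.090 unpaired, and 0.058 and 0.107 paired. Leaving out 1 library at a time gave an unpaired r of 0.0633 to 0.153 for neomycin and -0.0703 to 0.132 for vancomycin. Of the 64 genes raised by neomycin in microglia by the paired model and tested in cord, 57 had a positive log2 fold change in cord, with a median of 0.34 (quartiles 0.10 and 0.78), and of 24 lowered genes 18 had a negative one. Of the 72 genes raised in cord and tested in microglia, 59 had a positive log2 fold change in microglia, with a median of 0.43. Of the 19 genes lowered in cord and tested in microglia, 12 had a negative one there, and the median of the 19 was -0.11. In both tissues 22 genes were raised and 1 was lowered, where independent lists of these sizes would share 0.389 and 0.0384, and 0 genes were called in opposite directions in the paired edgeR models.

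**Figure D3:**
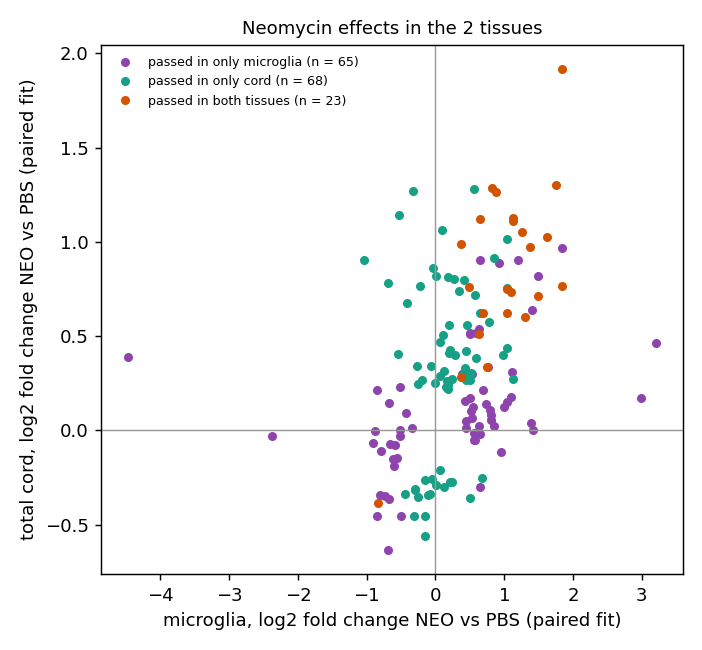
Paired log2 fold change of neomycin against PBS in microglia (horizontal axis) and in total cord (vertical axis) for genes tested in both. Shown are genes that passed an adjusted p of 0.05 only in microglia (65 genes), only in cord (68 genes) or in both tissues (23 genes). Of the 23 genes that passed in both, 22 lie at the upper right and 1 at the lower left.

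Whether an antibiotic acted differently in microglia and in cord was tested in the model of all 21 libraries. For neomycin edgeR called 0 of 15546 genes unpaired, with 438 at an unadjusted p under 0.05, and DESeq2 and limma-voom called 0 each; the count was 1 without PBS replicate 5 of the microglia. For vancomycin edgeR called 0, with 234 at an unadjusted p under 0.05, DESeq2 1 and limma-voom 0. The paired model called 30 genes for neomycin (12 with a higher and 18 with a lower fold change in microglia) and 18 for vancomycin, all lower in microglia. Without all libraries of number 1, 2, 3 or 5 the counts were 1, 79, 0 and 117 for neomycin and 0, 38, 0 and 24 for vancomycin. Of the 18 genes 17 were higher in cord than in microglia in PBS animals, and 13 of the 18 were also among the 30.

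**Figure D4:**
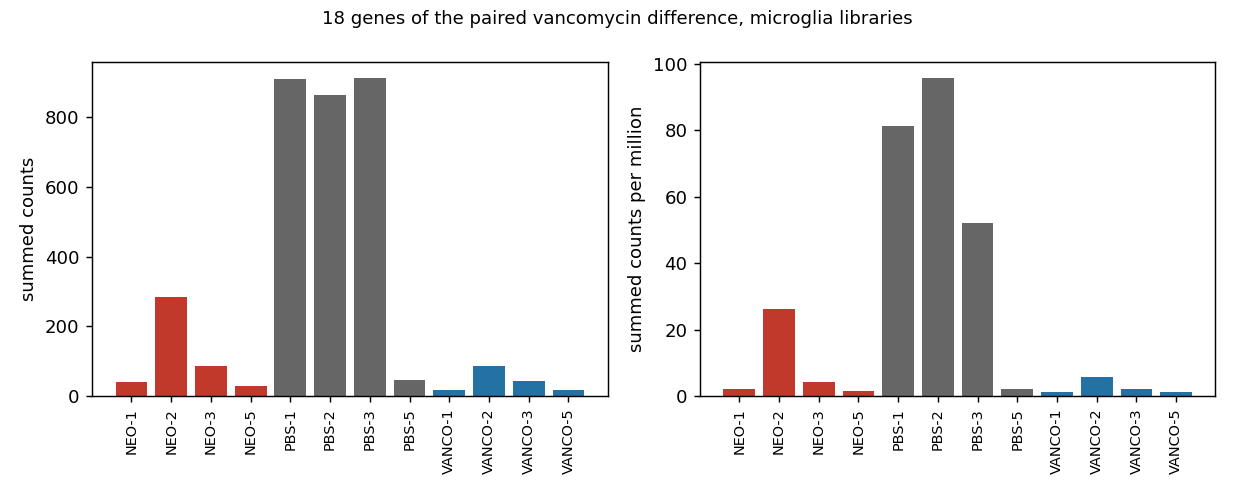
Summed counts (left) and summed CPM (right) of the 18 genes called for vancomycin by the paired test of the difference between tissues, as 1 bar per microglia library coloured by treatment. PBS replicates 1, 2 and 3 lie at 81.3, 95.8 and 52.2 CPM, PBS replicate 5 at 2.05 CPM and the 4 vancomycin libraries at 1.16 to 5.55 CPM.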

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

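The tests of depth and of neomycin for the cord-enriched share, of a higher share of microglia in the cord pellets and of depth for the cord genes, and the 3 tests on the vancomycin difference between tissues were chosen after the results they address had been seen. Each measure was examined in each treatment group of 4 microglia libraries for a library far from the others. Of these 24 combinations 6 had one (by Dixon's ratio of gap to range), and chance gives about 1 in 20 for a single one. The combinations reuse the same libraries and include printed genes chosen for their calls, so they are not independent. VANCO replicate 3 had a total count of 20936827 against 14706297 to 15319914 in the other vancomycin libraries. The cord-enriched share was 2.57% in NEO replicate 2 against 0.0367 to 0.0986% in the other neomycin libraries, and 0.306% in PBS replicate 2 against 0.0850 to 0.112% in the other PBS libraries. The microglia-enriched share was 23.3% in NEO replicate 2 against 32.0 to 33.4%. ENSRNOG00000036913 had 131 CPM in PBS replicate 2 against 174 to 181 CPM, and ENSRNOG00000017869 had 445 CPM in NEO replicate 2 against 610 to 623 CPM. Of these 6 outlying values 5 belong to NEO replicate 2 or PBS replicate 2. The paired tests of a difference between microglia and cord called 30 genes for neomycin and 18 for vancomycin. Without number 1 or 3 these counts were 1 and 0 for neomycin and 0 and 0 for vancomycin, without number 2 they were 79 and 38, and without number 5 they were 117 and 24.

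The high share of cord-enriched counts in NEO replicate 2 was weighed first. Neomycin as the source is argued against by the other 3 neomycin libraries, whose highest share, 0.0986%, lay below the 0.306% of PBS replicate 2. The only shallower microglia library, PBS replicate 2 with 9020480 counts against 10847891, had 0.306%, which argues against low depth, and without its 10 most counted cord-enriched genes NEO replicate 2 still had 0.949% against at most 0.158% in the others, which argues against a few genes. RNA from other cord cells in the sorted sample may be the source: 100 of the 100 most abundant cord-enriched genes were higher in it than in the other 11 microglia libraries, although the CD45low CD11b+ gate would remove most such cells. Whether such RNA accounts for the whole fall of the microglia-enriched share in NEO replicate 2 was not tested. Leaving out this library moved the count of neomycin genes in microglia from 5 to 15 unpaired and from 94 to 300 paired.

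The genes raised by neomycin in total cord in the paired model were weighed next; their count was 100 with the lowered genes, 65 without NEO replicate 1 and 57 without PBS replicate 3. A higher share of microglia in the neomycin pellets is argued against by the 882 microglia-enriched genes, whose median log2 fold change was 0.0321 (-0.01 to 0.08 over the 3 pairs) while the raised gene that changed least had 0.22. Greater depth was examined by thinning the 9 cord libraries to equal depth. Over 5 thinnings the median log2 fold change was 0.62 to 0.65 against 0.62, and 68 to 73 of the 76 genes were called again. The 3 to 8 others moved from medians of 0.30 to 0.47 (median SE 0.07 to 0.11) to 0.27 to 0.42 (0.07 to 0.11). Their edgeR adjusted p was at most 0.123. Random thinning leaves the expected fold of a gene unchanged, and the genes were chosen from the same counts. This result therefore could not decide whether depth was the cause. A first limit of 9 in 10 genes called again was missed at 68. A limit of 0.2 for genes raised without number 2 was also missed in that pair (0.16, quartiles -0.02 and 0.53). These genes had 0.33 in their own fit. Those raised without number 1 or 3 had 0.47 and 0.58 in the pair left out against 0.91 and 0.88. The median was thus lower in each pair left out, and both limits remain missed. The neomycin library was the deeper one in every pair, with 1.055, 1.0405 and 1.4977 times the PBS counts in pairs 1, 2 and 3. Pairs 1 and 2 were thus close to equal depth. Of the genes raised without the pair, 60 of 71 were higher in pair 1, 144 of 204 in pair 2 and 42 of 46 in pair 3. For these genes, the values in pairs 1 and 2 argue against depth as the whole cause, although the median of 0.16 in pair 2 was small. A microglial response carried by the microglia in the cord was tested with a limit of 0.30. It applied to the median excess of the observed over the carried log2 fold change. The excess was 0.43 (quartiles 0.27 and 0.77, 72 genes) with microglia taken as 4.83% of cord RNA. That share was the median cord-to-microglia ratio of the 882 microglia-enriched genes in PBS. They were chosen as at least 8-fold higher in microglia of the same PBS groups, so the cutoff partly set it. If all cord RNA of the 72 genes came from microglia, the excess would be 0.09 (quartiles -0.20 and 0.47). The limit thus rested on an assumed profile. A carried response and a response of other cord cells to neomycin cannot be told apart.

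The 18 genes behind the paired vancomycin difference were weighed last; without numbers 1, 2, 3 and 5 the edgeR test called 0, 38, 0 and 24 genes, with 443, 950, 417 and 740 at an unadjusted p under 0.05, while the median log2 fold difference of the 18 genes was -4.01, -4.86, -4.64 and -4.62 (median SE 0.68, 0.69, 0.80 and 0.63) against -4.51 (0.62) with all numbers, and the unpaired test called 0 with 234 at an unadjusted p under 0.05, against 1 in DESeq2 and 0 in limma-voom. Vancomycin as the cause stays open: PBS replicates 1, 2 and 3 had summed values of 81.3, 95.8 and 52.2 CPM, above the 1.16 to 5.55 CPM of the vancomycin libraries, but PBS replicate 5 had 2.05 CPM, and NEO replicates 1, 3 and 5, which had no vancomycin, 2.07, 4.24 and 1.36 CPM, although NEO replicate 2 had 26.1 CPM (283 counts). Whole-cord RNA in those PBS libraries is argued against by the cord-enriched genes. The 100 most abundant had a median vancomycin log2 fold change in microglia of -0.66 against -4.64 for the 18 genes. They were chosen for low values in the same PBS microglia libraries, so this contrast is partly built in. All 1646 held 29.9 to 33.2% of counts in PBS cord but 0.0850 to 0.306% in PBS microglia. The 18 genes had 322 to 642 CPM in PBS cord against 52.2 to 95.8 CPM in PBS replicates 1, 2 and 3 of the microglia. An equal number of stray reads from another source in PBS replicates 1, 2 and 3 could be the cause. The summed counts of the 18 genes were 910, 864 and 913, within counting error of equal. Their coefficient of variation was 3.07% against 29.0% for CPM. A second set of 66 genes had 5051, 4428 and 5214, beyond counting error. It came from another grouping of the neomycin and PBS libraries, which called 69 genes, 12 of them among the 18. The 66 were those lower in NEO replicates 1, 3 and 5 with PBS replicate 5. High values in PBS replicates 1, 2 and 3 were thus built into that set. No label gives a lane, index or preparation day, so vancomycin, stray reads and another kind of tissue in those samples cannot be told apart for these genes.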

How the results depend on the processing

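Every alternative within the paired models, those without all libraries of a number, every alternative for r between tissues or antibiotics (the replicate block included), and the unpaired ones without number 2 were chosen after the data had been seen; the others were planned. The alternatives for the gene list tests, the interferon score and the rule for naming genes were not run, since the files give no symbols. Where a cause is not given below, the cause was not tested.

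The replicate block moved the count of called genes from 5 to 94 for neomycin against PBS in microglia, from 0 to 21 for neomycin against vancomycin in microglia, from 0 to 100, 1 and 64 for neomycin against PBS, vancomycin against PBS and neomycin against vancomycin in cord, and from 0 to 30 and 18 for the neomycin and vancomycin differences between tissues. It left 0 genes for vancomycin in microglia and 13359 in place of 13065 for microglia against cord, and changed no other call. It moved r between tissues for neomycin from 0.102 to 0.137 and r between antibiotics in microglia from 0.348 to 0.591.

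For neomycin against PBS in microglia, where 5 genes were called unpaired, DESeq2 called 66, RLE factors 2 (2 higher), upper quartile factors 12, no filter 9, all 21 libraries 19, only the compared groups 0 and the libraries without number 2 gave 9. For neomycin against vancomycin in microglia DESeq2 gave 16 and all 21 libraries 3, and for vancomycin DESeq2 gave 5. In cord DESeq2 gave 26 for neomycin against PBS and 25 against vancomycin, no filter 15 and 13, all 21 libraries 2 against PBS, and upper quartile factors 1 against vancomycin. DESeq2 gave 1 for the vancomycin difference between tissues. Apart from leaving out a library, the other planned counts stayed at 0 or within 1.5 times, and microglia against cord stayed between 12163 and 13732.

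In the paired models DESeq2 gave 314 genes for neomycin, 38 for vancomycin and 84 for neomycin against vancomycin in microglia, 57, 0 and 41 in cord in that order, and 172 and 68 for the neomycin and vancomycin differences between tissues. limma-voom gave 0 for vancomycin in cord and 5 and 0 for those differences. On the simulated counts for neomycin, 14.1% of paired DESeq2 calls were false in microglia and 4.97% in cord. For the neomycin difference between tissues this share was 11.05%. Paired edgeR had 3.74%, 10.3% and 4.18% in that order. Without a filter, vancomycin gave 6 and neomycin against vancomycin 37 in microglia, and the cord counts were 251, 8 and 173. With the cord-enriched share as a covariate the microglia counts were 603, 57 and 64, and 92 of the 94 neomycin genes were among the 603. Without genes at least 8-fold higher in cord the vancomycin difference gave 8. RLE and upper quartile factors kept each paired count within a tissue within 1.5 times, and 92 and 94 of the 94 genes were called again.

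Leaving out 1 library at a time, unpaired counts ranged from 0 to 15 for neomycin in microglia, from 0 to 1 for neomycin against vancomycin in cord and for the neomycin difference between tissues, and from 12655 to 13018 for the tissues; the others stayed at 0 in edgeR. Leaving out 1 library or number, paired counts ranged from 0 to 300, 0 to 7 and 0 to 75 in microglia, from 57 to 398, 0 to 5 and 36 to 129 in cord, and, by number, from 0 to 117 and 0 to 38 for the differences between tissues. r between tissues ranged from 0.0633 to 0.153 for neomycin and from -0.0703 to 0.132 for vancomycin, which was negative without PBS replicate 2 (-0.0703) or VANCO replicate 3 (-0.0447) of the cord. r between antibiotics ranged from 0.171 to 0.822 in microglia and from 0.283 to 0.694 in cord.

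In all, 174 of 274 alternative counts were within 1.5 times of the reported one. Many of the 174 were 0 against a reported 0, and others were the large counts of microglia against cord. The tally therefore says little about how stable the treatment counts above 0 were. Each of the 4 printed genes kept its direction in every alternative. ENSRNOG00000036913 kept its call in 11 of 18 alternatives (log2 fold change 0.95 to 1.22, adjusted p 1.99e-14 to 0.130) and ENSRNOG00000017869 in 7 of 18 (-0.77 to -0.64, 1.61e-09 to 0.312). ENSRNOG00000022839 passed in cord in 3 of 16 (1.65 to 2.16, 2.14e-06 to 1) and ENSRNOG00000016837 only with the block, in 1 of 15 for neomycin (-2.30 to -1.14, 0.000592 to 1) and 1 of 16 for vancomycin (-2.39 to -1.20, 0.00614 to 1); DESeq2 gave it no adjusted p for neomycin. Genes with few counts are limited by depth: 3 counts correspond to 0.134 CPM in the deepest microglia library and 0.333 CPM in the shallowest.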

Other observations

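The test of genes shared by the tissues was chosen after the calls had been seen; the tests of other groupings, of r between tissues and of numbers across tissues were fixed before their results were seen. Other groupings of the same libraries were tested for every count. For neomycin against PBS in microglia, 2 of the 35 ways to divide the 8 libraries gave at least the 5 genes of the unpaired model, so chance was not excluded. The other grouping called 69 genes and set PBS replicates 1, 2 and 3 with NEO replicate 2 apart from NEO replicates 1, 3 and 5 with PBS replicate 5, which points to a structure of these samples. Of those 69 genes 65 were higher in cord, 12 were among the 18 genes of the vancomycin difference, 0 were among the 5 neomycin genes and 2 among the 94 of the paired model. The count of 5 was 0 without NEO replicate 1 or 3 or any 1 of the 4 PBS libraries, 2 without NEO replicate 5 and 15 without NEO replicate 2. Each of the other microglia comparisons called 0 genes unpaired in edgeR, as did 35 of 35 groupings (highest other 0); every grouping gives at least 0, so this says nothing about chance. In these comparisons 108 and 269 genes had an unadjusted p under 0.05 for vancomycin against PBS and neomycin against vancomycin, DESeq2 called 5 and 16 and limma-voom 0 and 0. The 3 cord comparisons called 0 genes unpaired in edgeR in 10 of 10 groupings (highest other 0), which says nothing about chance either, and 10 are too few for a share under 0.05; 400, 124 and 331 genes had an unadjusted p under 0.05, and DESeq2 called 26, 0 and 25 and limma-voom 0. For microglia against cord, 1 of 35 groupings gave as many genes (13065, highest other 11013), so chance was excluded.

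In the paired models only groupings that part every pair were compared. In microglia these were 8, too few for a share under 0.05: neomycin gave 94 genes in the real grouping (1 of 8; highest other 0), neomycin against vancomycin 21 (1 of 8; highest other 0) and vancomycin 0 in edgeR (8 of 8; highest other 0), with 365 at an unadjusted p under 0.05, 38 in DESeq2 and 0 in limma-voom. In cord there were 4, also too few: neomycin gave 100 (1 of 4; highest other 1), vancomycin 1 (2 of 4; highest other 1) and neomycin against vancomycin 64 (1 of 4; highest other 2). For the differences between tissues the unpaired edgeR counts were 0, which 100 of 100 drawn groupings reach by definition for neomycin (highest other 295) and for vancomycin (highest other 0), with 438 and 234 genes at an unadjusted p under 0.05, 0 and 1 in DESeq2 and 0 in limma-voom. In the paired model 26 of 64 groupings gave at least the 30 neomycin genes (highest other 243) and 16 of 64 at least the 18 vancomycin genes (highest other 35), so chance was not excluded for either, and the groupings with 295 and 243 genes point to a structure of the samples. Without number 1, 2, 3 or 5 the paired neomycin counts were 20, 211, 0 and 19 in microglia, and without number 1, 2 or 3 they were 78, 398 and 59 in cord.

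The idea that neomycin changes some of the same genes in microglia and cord was tested by exchanging the neomycin and PBS libraries within numbers, in all 64 ways that count a reversal of both tissues once. Since the other assignments call almost no genes, lists of equal length were compared in place of called genes: the 100 genes with the lowest paired p in each tissue, chosen anew in each assignment. The real assignment shared 26 genes of 1 direction and the highest of the others 5, where independent lists would share 0.4215, an exact share of 0.0156, which is the smallest that 64 assignments can give. Lists of 50 genes shared 13 (highest other 1) and lists of 200 genes 36 (highest other 16). This is consistent with some shared response, as a hypothesis from the data that raised it, and microglia within the cord pellets could carry it. Over all 11862 genes, r was 0.153 for neomycin (highest other 0.188) and 0.0864 for vancomycin (highest other 0.0936), an exact one-sided share of 0.0625 for each. The limit of 0.05 set for this test was wrong as a bound against the idea, since a share that misses it excludes nothing with 64 assignments.

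Whether a number marks the same animal in both tissues was tested on the neomycin differences within numbers, with the vancomycin differences beside them. The 3 same-number pairs of microglia and cord had a mean r across genes of -0.0023 (-0.0773 to 0.0585), and the 9 other pairs one of 0.0889 (0.0066 to 0.208). For vancomycin these were 0.0352 (-0.0172 to 0.0762) and 0.0297 (-0.023 to 0.0982), in the opposite order. The ranges overlap for both antibiotics, so the bound that same-number pairs lie higher on average decided nothing, and the labels do not say which tissues came from the same animal.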
